A study of Caenorhabditis elegans with 2 samples.

How the data were processed

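ChIP-seq libraries of 2 biological replicates of late embryos from a line expressing ODD-2 with a C-terminal GFP-FLAG tag, precipitated with an anti-GFP antibody, form 1 group, per the labels. Each deposited peak file lists regions with a signal per region (the signal column of the narrowPeak format), computed by the authors against a control file, per the file list deposited with the samples. The aligner, the peak caller and their versions are not given in the sources used here. The column that the format keeps for a q-value was taken as a score in the deposited files, because it holds values below 0 (109 of the 260 IDR peaks, and 99.5% of the pooled candidate regions), and no comparison rests on it. Each of the candidate sets (replicate 1, replicate 2 and pooled) holds 30000 regions that served as input to the IDR step, per the deposited file names. The IDR peak set of 260 regions, labelled optimal, was derived by the authors from both replicates. Membership does not by itself show recovery in each replicate. A candidate summit within 100 bp was found in replicate 1 only for 12 of the peaks and in replicate 2 only for 9. Pooled signals run from 24.6 to 772 and replicate signals from 13.2 to 371 (replicate 1) and 12.7 to 458 (replicate 2), so no test set signal levels of 1 file against those of another. Where replicate signals are given side by side, differences in scale between the files were not removed. Both builds, ce10 and ce11, were deposited. Only ce11 positions were annotated and no position was converted between builds.

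All 260 IDR peaks were found with identical bounds among the pooled candidate regions. The 276 pooled candidates that overlap an IDR peak by at least 1 bp were set apart, and the other 29724 served as background. A region was placed by its summit. Genes came from Ensembl release 115 for the same assembly, and names of mitochondrial genes from the RefSeq annotation. Many C. elegans transcripts are trans-spliced, so an annotated 5' end can lie downstream of the true start of transcription. A summit 1000 bp upstream to 200 bp downstream of a protein-coding 5' end was called promoter, and the rest fell in order into 5' UTR, coding sequence, 3' UTR, intron, noncoding gene and intergenic. A peak was assigned to the nearest protein-coding 5' end when it lay at most 2000 bp upstream or 500 bp downstream of it. Short RNA genes are annotated tRNA, snRNA, snoRNA and rRNA genes, and a summit within 200 bp of one counted as near it. Words were searched on both strands within 100 bp of the summit. Summits within 100 bp of each other counted as shared between replicates.

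Shares were compared with two-sided Fisher's exact tests in scipy 1.17.1 (numpy 2.4.6, pandas 2.3.3, Python 3.11.15, figures with matplotlib 3.10.9), with conditional odds ratios and exact 95% intervals. An odds ratio above 1 means more frequent at IDR peaks. For the 2080 words of 6 bases the odds ratio was computed with 0.5 added to each cell. Benjamini-Hochberg adjustment ran over the 2080 words, the 19 gene lists, or the 4 words fixed in advance with their 4 reverse-order controls, at 0.05. Regions are not biological replicates, and neighbouring regions are not independent, so these p-values describe where regions lie and not variation between animals; each share was also computed from the 260 strongest regions of each replicate alone. GC-matched backgrounds took 20 regions per peak in bins of 5 percentage points, and peaks in bins with too few regions were left out (225 of 260 remained); the same peaks were also compared with 20 unmatched draws of as many regions. For odd-2, candidate signal within 20 kb of the gene's midpoint was summed and ranked among windows of 40 kb over the nuclear genome.

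The tests, gene lists, words and most alternatives were chosen before the data were examined, as was the rule for named items: assigned genes of the 20 IDR peaks with the highest signal, odd-1 and odd-2, up to 4 members of each list with the strongest peak, and the 5 words of 6 bases with the smallest adjusted p and an odds ratio above 1. The strongest nuclear peaks, hlh-1, pal-1, CCGCAC and the short RNA genes named were chosen after their values were seen. So were the separation into peaks near short RNA genes and other nuclear peaks, and the alternatives without mitochondrial regions, without regions near short RNA genes, without regions within 50 kb of odd-2 and with unmatched draws. The other alternatives were each replicate alone, the stronger 130 IDR peaks, the strongest 5000 other regions as background, other promoter, gene and word windows, and the ce10 files. The word, list and share tests were tested on simulated data: 10 of 10 planted words were recovered among 2080, and 0 words were called when none was planted. Simulated peaks and background had the same GC content. In the data the median was 46.8% in peaks near short RNA genes, 40.3% in other nuclear peaks and 34.3% in the background. The simulation therefore does not show how many words GC content alone would call. Text lists of parent files in the deposit hold no measurements and were read for provenance only.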

Results

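ODD-2, a zinc-finger protein of the Odd-skipped family, was mapped by ChIP-seq in late embryos of Caenorhabditis elegans hermaphrodites of strain OP405, which carries a transgene for ODD-2 with a C-terminal GFP tag. Chromatin was sheared by sonication and precipitated with an anti-GFP antibody. The data hold 1 group with 2 biological replicates, so the question is where the tagged protein was recovered and how far both replicates gave the same places. For each replicate and for the pooled reads, 30000 candidate regions with a signal value were deposited. A further set of 260 peaks passed the irreproducible discovery rate (IDR) threshold and is called IDR peaks here. Read depth is unknown, because the files give no read numbers. No library from untagged worms was analysed here. The background in the main comparisons was therefore the 29724 pooled candidate regions that do not overlap an IDR peak. For each replicate alone it was the other 29740 candidate regions of that replicate. All positions are 1-based on build ce11. The comparisons restricted to nuclear peaks near or away from short RNA genes, and the list of the strongest nuclear peaks, were chosen after the values were seen, as were the unmatched draws beside the GC-matched word counts.

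The strongest nuclear IDR peaks lay just upstream of protein-coding genes and beside small nucleolar RNA (snoRNA) genes. The highest nuclear signal was 340.6, 48 bp upstream of idhg-1 (WBGene00009440; III, 4568584 to 4568913), an isocitrate dehydrogenase gene, with a signal of 166 in replicate 1 and 178 in replicate 2. K05C4.2 (pooled signal 288; I, 14721478 to 14721807), atx-2 (265; III, 10461150 to 10461479), the ataxin-2 gene, nmad-1 (218), ftt-2 (207), a 14-3-3 gene, ears-2 (204), a glutamyl-tRNA synthetase gene, and krr-1 (182), a ribosome assembly gene, followed. F39G3.3 (210), spe-48 (187), C46F11.4 (180), C16C10.4 (172) and B0495.9 (170.4) had peaks of like height at their promoters. Of the 20 strongest nuclear peaks, 12 lay at promoters away from any short RNA gene, 6 near a snoRNA gene and 1 near a tRNA gene. The remaining peak lay inside hlh-1, the muscle MyoD gene, and had no counterpart in replicate 2 within 100 bp of its summit. Of the 20 highest signals of all, 16 were mitochondrial. The highest lay inside ND5 (772; 295 in replicate 1 and 458 in replicate 2), and the 16 included peaks assigned to COX3 (733), CYTB (670), ATP6 (502), ND4L (489), ND4 (438), COX1 (421), ND3 (327), COX2 (312) and ND1 (267). Besides these, the 20 highest held the idhg-1, K05C4.2 and atx-2 peaks and a snoRNA peak in an intron of frm-7 (271; V, 12303473 to 12303802).

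The mitochondrial genome carried 23 IDR peaks, out of 24 pooled candidate regions on it. They covered 48.9% of its 13794 bp and held 26.3% of the summed signal of all IDR peaks. The cause of these mitochondrial peaks was not tested, so their height does not mark them as sites of ODD-2. The nuclear peaks were spread as 29 on chromosome I, 33 on II, 43 on III, 33 on IV, 33 on V and 66 on X.

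The replicates shared part of their strongest regions. Of the 260 strongest regions of replicate 1, 146 (56.2%, 95% exact binomial interval 49.9 to 62.3) had a summit within 100 bp of a summit among the 260 strongest of replicate 2. For the next 260 regions of each replicate the count was 13 (5.0%), and for the weakest 260 it was 1. Each set was matched only to the set of the same ranks in the other replicate, so a region with a counterpart at another rank did not count, which lowers both of these counts. Without mitochondrial regions 132 of the 260 strongest (50.8%, interval 44.5 to 57.0) were shared. The IDR peaks were derived from these same replicates, so the values that follow for them are no separate measure of agreement. Of these peaks, 239 (91.9%) had a candidate summit within 100 bp in both replicates, 12 in replicate 1 only and 9 in replicate 2 only. Across the 218 nuclear IDR peaks found in both, Spearman's rho between the replicates' signals was 0.593, a value across regions, which are not independent replicates. Among the 1000 strongest regions of each replicate 23.9% were shared. Over all 30000 candidate regions it was 30.1%, a share that also rises by coincidence as more regions are compared.

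**Figure D1:**
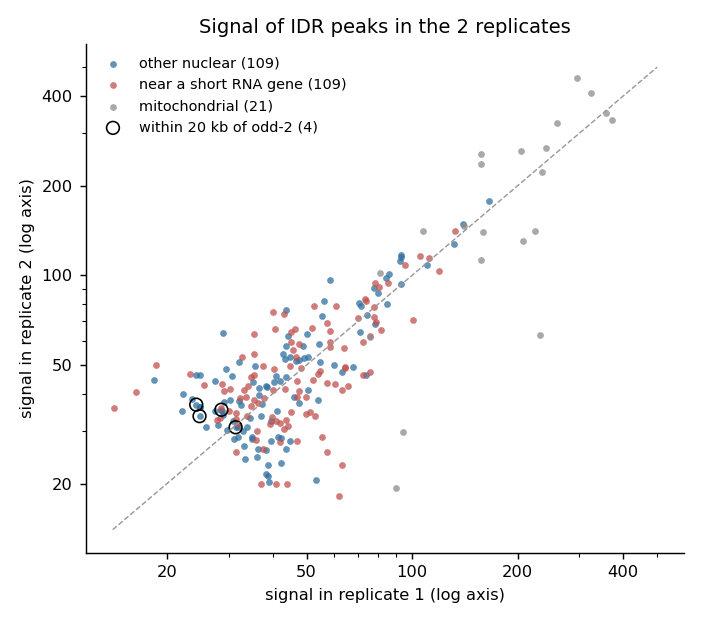
Signal of each IDR peak in replicate 1 (x axis, log) and replicate 2 (y axis, log) for the 239 peaks with a candidate summit in both; colours separate mitochondrial, short RNA gene and other nuclear peaks, circles mark peaks within 20 kb of odd-2, and the dashed line marks equal signal. Mitochondrial peaks reach the highest signals in both replicates, and the 4 circled peaks lie among the weakest.

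Many of the nuclear IDR peaks, 116 of 237, sat at genes for short noncoding RNAs. These 116 (48.9%) had a summit within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene, against 306 of 29723 other candidate regions (1.03%; odds ratio 92.0, 95% interval 69.0 to 123, Fisher's exact test, two-sided, p = 1.81e-153). With the mitochondrial regions the count was 127 of 260 (odds ratio 91.4, interval 69.3 to 121, exact p = 8.48e-167). Peaks near tRNA genes numbered 78 (32.9% against 0.703%, odds ratio 69.2, interval 50.4 to 94.6). Peaks near snoRNA genes numbered 36 (15.2% against 0.276%, odds ratio 64.7, interval 41.4 to 99.4), and 2 peaks lay near snRNA genes. None of the 20 nuclear rRNA genes had a peak, nor did any have a candidate region. Counted by gene, 85 of 612 nuclear tRNA genes (13.9%, interval 11.2 to 16.9) and 37 of 346 snoRNA genes (10.7%, interval 7.64 to 14.4) had an IDR peak within 200 bp. The 260 strongest regions of replicate 1 touched 76 of the tRNA genes and those of replicate 2 touched 74, with 52 in common. In 41 of the 78 tRNA peaks the summit lay inside the tRNA gene itself, and in 8 of the 36 snoRNA peaks inside the snoRNA gene. The strongest snoRNA peaks lay in an intron of frm-7 (C51F7.3 and C51F7.4, signal 271), upstream of sre-23 (ZK265.10, 228), between genes on V (T06C12.16, 225) and in an intron of cutl-18 (T03F7.8, 223). The strongest tRNA peak lay in an intron of fli-1 (signal 170.7; III, 8678377 to 8678706), and another lay in him-4, the hemicentin gene (155; X, 9743504 to 9743833). In each replicate alone the 260 strongest regions, mitochondrial ones included, gave shares near short RNA genes of 42.3% (replicate 1) and 43.8% (replicate 2).

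Chromosome X held more IDR peaks than its share of candidate regions, and no excess was seen away from short RNA genes. X carried 66 of 237 nuclear peaks (27.8%) against 17.6% of other candidate regions (odds ratio 1.81, interval 1.34 to 2.42, Fisher's exact test, p = 1.04e-04), with 23.7% among the strongest regions of replicate 1 and 28.5% among those of replicate 2. Of the 66 peaks, 46 were near a short RNA gene, and X holds 276 of the 612 nuclear tRNA genes. Away from short RNA genes X had 20 of 121 peaks (16.5% against 17.4%, odds ratio 0.937, interval 0.549 to 1.53, exact p = 0.904). In the stronger 130 IDR peaks the X excess did not pass the test (odds ratio 1.34, exact p = 0.206).

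**Figure D2:**
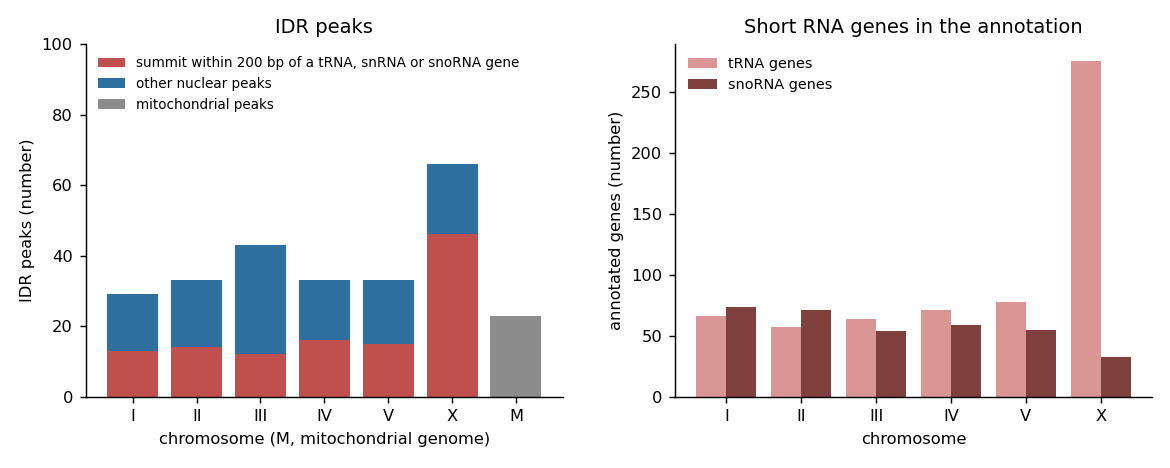
Left, number of IDR peaks per chromosome (y axis), split into peaks near a tRNA, snRNA or snoRNA gene, other nuclear peaks and mitochondrial peaks; right, number of annotated tRNA and snoRNA genes per nuclear chromosome (y axis). X stands out on the left with 46 peaks near short RNA genes and on the right with 276 tRNA genes.

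Away from short RNA genes, most nuclear peaks were at promoters. The peaks were not compared with regions bound by many factors or with regions of known artefact signal. Peaks at promoters, near short RNA genes or on the mitochondrial genome therefore cannot be ascribed to ODD-2 in particular. The promoter was taken as 1000 bp upstream to 200 bp downstream of a protein-coding 5' end. Over all 260 peaks 131 were at promoters (50.4% against 29.9%, odds ratio 2.38, interval 1.85 to 3.07, Fisher's exact test, p = 7.78e-12), with 47.7% in replicate 1 and 50.4% in replicate 2. These shares include mitochondrial regions, of which the pooled background holds 1. Among the 237 nuclear peaks 111 were at promoters (46.8% against 29.9%, odds ratio 2.07, interval 1.59 to 2.69, exact p = 4.67e-08). Among the 121 nuclear peaks away from short RNA genes 85 were at promoters (70.2% against 29.9%, odds ratio 5.54, interval 3.71 to 8.44, exact p = 7.92e-20). Their summits lay at a median of 152 bp upstream of the nearest 5' end, and the 85 peaks belonged to 85 different genes. Coding sequence held 3 of the 121 peaks (2.48% against 14.9%, odds ratio 0.145, interval 0.0295 to 0.436) and introns 16 (13.2% against 29.1%, odds ratio 0.371, interval 0.205 to 0.632). Peaks near short RNA genes were at promoters in 26 of 116 cases and in introns in 47.

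No list of tissue genes had an assigned peak, though few were to be counted at this number of peaks. In all, 161 of the 260 peaks were assigned to a protein-coding gene, 151 different genes. Not 1 of 19 gene lists passed Fisher's exact test after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. The first was the ribosomal protein genes, with rps-28 (signal 91.7), rpl-3 (90.2) and rpl-15 (67.9), all at promoters (3 of 260 peaks against 0.195%, odds ratio 5.97, interval 1.19 to 18.5, p = 0.016, adjusted p = 0.28 by Fisher's exact test). The second was the collagen genes, with col-85 (139), col-185 (94.7) and col-94 (90.9), and all 3 of these peaks also lay near a short RNA gene (odds ratio 4.68, interval 0.937 to 14.4, p = 0.0295, adjusted p = 0.28 by Fisher's exact test). Once regions near short RNA genes and mitochondrial regions were left out, the ribosomal protein list passed (odds ratio 13.6, interval 2.68 to 42.7, adjusted p = 0.0334 by Fisher's exact test). Among the heat shock genes only hsp-1 had a peak (84.7), and among the nuclear receptors only nhr-255 (73.0), also near a short RNA gene. The other 15 lists had no assigned peak: intestine, pharynx, body wall muscle, epidermis, neuron, germline, excretory system, Wnt pathway, Notch pathway, Hox genes and cofactors, the Odd-skipped family, ceh homeobox genes, hlh genes, vacuolar ATPase and histones. Each of these 15 lists held at most 0.161% of the other candidate regions, so fewer than 1 peak per list corresponds to the background rate, and their zeros do not show that such genes were avoided. A peak counted for a gene only near its 5' end. The peak in an intron of pal-1, a caudal-type homeobox gene (63.8; III, 4805385 to 4805714), was not assigned; of the 4 peaks inside hlh-1 none was assigned to hlh-1, and 2 went to B0304.2. In 50 simulated draws of 260 peaks, 2 planted lists with genes made 8 times as frequent were called 58 times of 100. Every simulated peak had a gene, whereas 161 of the 260 peaks had one here. The planted lists also held a larger share of the background than any of these 15 lists. The simulation therefore overstates how readily such a list would be called.

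Several DNA words were more frequent around the summits of IDR peaks than around those of other regions. CGAACC (25.8% of all IDR peaks against 3.44% of other regions, odds ratio 9.79) and GTTCGA (27.3% against 7.19%, odds ratio 4.87), which match the B box inside tRNA genes, led together with GCGCAC (19.2% against 2.90%, odds ratio 8.02), CCGCCC (20.8% against 3.59%, odds ratio 7.09) and CGCACA (21.5% against 4.18%, odds ratio 6.34). In all, 397 of 2080 words of 6 bases were more frequent at IDR peaks and 160 less frequent, by Fisher's exact test with Benjamini-Hochberg adjustment. The largest adjusted p among the 5 named words was 4.52e-20. Overlapping words are counted separately. Against a background matched on GC content, with 225 peaks and 4500 regions, 139 words were more frequent. The same 225 peaks against 20 unmatched draws of as many regions gave 264 to 285 words, so part of the fall came with the reduced sets and part with the matching. The first part was not split further: the sets were smaller, and the peaks kept also differed, with 100 of 225 near a short RNA gene against 127 of 260. Near short RNA genes CGAACC was in 51.7% of peaks and in 36.3% of other candidate regions near such genes. In the other nuclear peaks it was in 5.79%, while CCGCCC was in 33.9%. GCGCAC and CGCACA were more frequent at both kinds of peak, each against other regions of its own kind (odds ratios 3.10 and 2.52 near short RNA genes, 12.6 and 10.2 away from them). No test compared the kinds of peak with each other.

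The main words fixed in advance for the Odd family and for GATA factors were not enriched, while a looser form of the Odd-family word gave a higher share on few peaks. The Odd-family word ACAGTAGC was in 1 of 260 peaks (0.385% against 0.357%, odds ratio 1.08, interval 0.027 to 6.20, Fisher's exact test, p = 0.607), so no difference was detectable with this number of peaks. Its reverse-order control CGATGACA was in 2 peaks. The looser form ACAGWAGC, also planned, was in 6 of 260 peaks (2.31% against 0.895%, odds ratio 2.62, interval 0.943 to 5.85, unadjusted exact p = 0.0319), and its control CGAWGACA in 3 (odds ratio 1.64, interval 0.333 to 4.91). In the nuclear peaks away from short RNA genes it was in 5 of 121 (4.13% against 0.901%, odds ratio 4.74, interval 1.5 to 11.5, unadjusted exact p = 0.00517), and the control in 3 (odds ratio 3.57, interval 0.720 to 10.8, exact p = 0.0561). The GATA-factor word TGATAA was less frequent at IDR peaks (10.4% against 17.2%, odds ratio 0.559, interval 0.360 to 0.836, p = 0.00282, adjusted p = 0.0226 over 8 words by Fisher's exact test), and its control AATAGT was not (13.8% against 14.5%, odds ratio 0.947). The GATA-word difference did not pass the test against regions of the same GC content, where 225 peaks remained and the word was in 12% of them against 13.8% (odds ratio 0.849, interval 0.541 to 1.29, exact p = 0.488). CACGTG (odds ratio 1.03, p = 0.855) and GAGAGAGA (odds ratio 1.57, p = 0.227) did not differ, whereas AGAGAGAG, set as the control of the latter and part of the same repeat, was more frequent (odds ratio 2.59, interval 1.22 to 4.89, adjusted p = 0.0297 by Fisher's exact test).

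**Figure D3:**
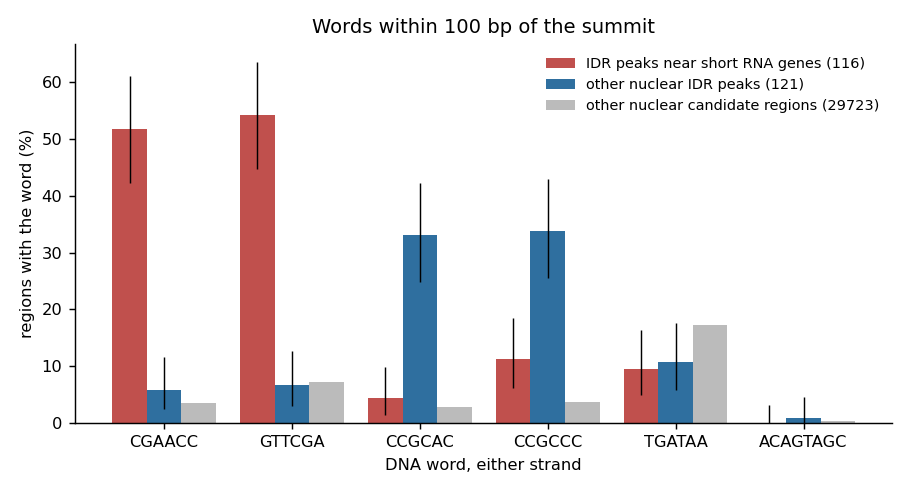
Share of regions with a word within 100 bp of the summit on either strand (y axis, percent) for 6 words (x axis), in IDR peaks near short RNA genes, other nuclear IDR peaks and other nuclear candidate regions; error bars are 95% exact binomial intervals. CGAACC and GTTCGA are in 51.7% and 54.3% of peaks near short RNA genes, and CCGCAC and CCGCCC in 33.1% and 33.9% of the other nuclear peaks.

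The region of odd-2 itself stood out as a broad stretch, while odd-1 had no peak nearby. Within 20 kb of odd-2 (WBGene00003846; X, 6159377 to 6160527) the pooled data held 32 candidate regions with a summed signal of 1350.4, or 42.2 per region, against a median of 12 regions and 385 over 2503 windows of 40 kb. The summed signal was above that of every such window in the pooled data and in replicate 2 (788 against a median of 203), and above 99.96% of them in replicate 1 (681 against 213). In this stretch 4 IDR peaks lay, at 6145041 to 6145370, 6164668 to 6164997, 6166152 to 6166481 and 6167850 to 6168179 on X, with signals of 64.3, 62.4, 67.2 and 62.4. The nearest was 4.31 kb upstream of the 5' end of odd-2, which lies on the minus strand, and none was assigned to odd-2 with the 2000 bp window. With a 5000 bp window 1 peak was assigned to the Odd-skipped family, against 2 of 29724 other regions. That list did not pass Fisher's exact test after adjustment (odds ratio 57.3, interval 0.969 to 1104, adjusted p = 0.281). For odd-1 (WBGene00003845; III, 7108313 to 7109769) the nearest IDR peak was 136.2 kb away, and no candidate region lay in the gene or within 2000 bp of it.

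**Figure D4:**
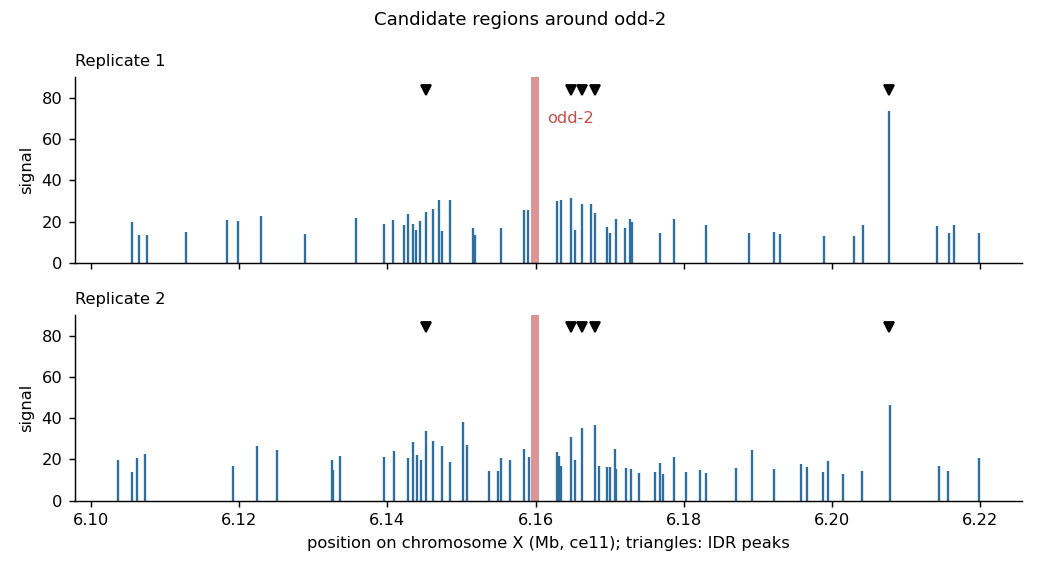
Signal of each candidate region (y axis) along 120 kb of chromosome X (x axis, Mb) in replicate 1 (top) and replicate 2 (bottom); the red band is odd-2 and triangles mark IDR peaks. Regions lie close together from about 20 kb on one side of odd-2 to 20 kb on the other in both replicates.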

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

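The alternatives without mitochondrial regions, without regions near short RNA genes and without regions near odd-2, the 50 bp window for short RNA genes, the GC-matched test of short RNA genes and the unmatched draw were chosen after seeing the data. Of 74 alternative values, 60 kept their direction and their side of the threshold, or stayed within the bounds set for counts and shares. The promoter and short RNA gene shares did so under every alternative run for them, though the odds ratio for short RNA genes fell from 91.4 to 39.7 with the strongest 5000 other regions as background and to 33.7 with the GC-matched one. Using one replicate alone gave odds ratios of 1.47 to 1.81 for the X share, 2.18 to 2.41 for promoters, 70.2 to 72.9 for short RNA genes, 0.562 to 0.578 for the GATA word and 1.1 to 2.19 for the Odd-family word, 292 to 310 enriched words, 0 gene lists in both cases, and 99.96 to 100 as the percentile of the odd-2 region. With the stronger 130 IDR peaks, the X share (odds ratio 1.34) and the GATA word (0.630) no longer passed the test and 194 words were enriched. Without mitochondrial regions and regions near short RNA genes, the X share turned to 0.937, the GATA word missed the threshold (0.579), 1 gene list passed and 159 words were enriched (121 peaks). The GATA word also missed the threshold with 200 bp either side (0.771) and with the GC-matched background (0.849), under which 139 words were enriched. An unmatched draw of the same size gave 0.655 and 271. Over 20 such draws the GATA odds ratio was 0.607 to 0.699 (exact p from 0.0161 to 0.0941) and 5 draws missed the threshold. The reduced sets alone, by their size or by which peaks were left out, can therefore also end this call. The Odd-family word turned to 0.961 with the strongest 5000 other regions as background and to 0.525 with 200 bp either side; with 1 peak holding the word, its direction is not determined. With ACAGWAGC in its place the odds ratio was 2.62 (6 peaks, exact interval 0.943 to 5.85, Fisher's exact p = 0.0319); the cause was not tested. Among the strongest 1000 regions 23.9% were shared between replicates. No paired analysis was possible because the data hold 1 group. Depth limits could not be set, since the files give no read numbers.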

Other observations

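The tests of candidate regions per Mb on X, of CCGCAC at promoters, of strongly transcribed genes, and of snoRNA peaks set against copied tRNA genes were chosen or reworded after the result was seen, and CCGCAC and GTTCGA were picked from these same data.

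A GC-rich word, CCGCAC, was in 37 of the 85 promoter peaks away from short RNA genes (43.5%). CCGCAC was in 40 of the 121 nuclear peaks away from short RNA genes (33.1% against 2.69% of other regions, odds ratio 17.9, interval 11.8 to 26.6), 37 of the 40 at promoters, and in 15 of the 20 strongest of these peaks, among them those of idhg-1, K05C4.2, atx-2, F39G3.3, ears-2, spe-48 and krr-1. A DNA word held by many of these promoters beyond their GC content may be part of what sets them apart. Against promoter regions of the same GC content CCGCAC was still more frequent (36 of 83 peaks, 43.4% against 4.82%, odds ratio 15.1, interval 8.95 to 25.3), and the same letters in reverse order, CACGCC, gave 2.81 (interval 1.25 to 5.76). Because CCGCAC was picked from these same peaks, its odds ratio is no separate support. A search over words of 8 bases was matched neither on GC content nor on promoters, and took all other nuclear regions away from short RNA genes as background. Median GC content was 40.3% in the 121 peaks and 34.3% in all other candidate regions, so GC-rich words could pass for that reason. Among 32896 words of 8 bases, 56 passed a Bonferroni correction in these 121 peaks, led by CGCCGCAC (18 peaks, 14.9% against 0.275%), CGTGCGGC (16 peaks, 13.2% against 0.170%) and CTCCGCCC (24 peaks, 19.8% against 1.01%). TTGCGAAA (23 peaks against 1.77% of other regions, odds ratio 13.0) was among them too and holds no CCGC. Which protein reads these words was not tested.

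Among regions near snoRNA genes, the IDR peaks more often held a tRNA-like B box word within 100 bp of the summit. Some snoRNA genes in nematodes are known to be transcribed by RNA polymerase III from internal promoters like those of tRNA genes, so recovery at both kinds of gene could reflect that machinery. Among candidate regions near a snoRNA gene and no tRNA gene, GTTCGA was in 12 of 36 IDR peaks (33.3%) and 11 of 81 other regions (13.6%, odds ratio 3.15, interval 1.11 to 9.06, Fisher's exact p = 0.0218). The word in reverse order, AGCTTG, was in 1 region of each set. Only 8 of the 36 summits lay inside the snoRNA gene, so the test does not place the word in the genes themselves. By isotype, alanine tRNA genes most often had a peak (11 of 34, 32.4%, against 12.8% of the others, odds ratio 3.25, interval 1.37 to 7.28), which missed the threshold after adjustment over isotypes (Fisher's exact test, adjusted p = 0.0778).

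Inside hlh-1, the muscle MyoD gene, lay 4 IDR peaks that only replicate 1 had within 100 bp. In replicate 1 a single stretch of II, 4520705 to 4522380, held summits with signals of 238, 138, 123, 56.2 and 18.8, and 2 of the 4 peaks lay in coding sequence and 2 in an intron. Replicate 2 had 1 summit in the gene, at 4521414 with a signal of 23.4, and none within 100 bp of the 4 peaks. The cause was not tested.

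The patterns at short RNA genes, on chromosome X and around odd-2 were weighed against technical explanations; the design has 1 group and names no biological explanation, so no biological explanation was tested for any of them apart from the B box word at snoRNA peaks. For the short RNA genes, GC content alone is argued against, since the odds ratio was 33.7 (interval 24.0 to 47.5) against regions of the same GC content. Reads shared between copies of tRNA genes are argued against for the snoRNA peaks only, since peaks near snoRNA genes and no tRNA gene were enriched as well (odds ratio 65.5, interval 41.9 to 101). These are the snoRNA peaks reported above, so the outcome was known beforehand and cannot decide the question for the tRNA peaks. The test replaced one on tRNA genes without a near-identical copy, which rested on 2 peaks (odds ratio 42.1, interval 4.14 to 237). For the tRNA peaks shared reads stay open. Genes of tRNAs with a unique sequence had a peak in 13 of 143 cases (9.09%) and copied ones in 72 of 469 (15.4%, odds ratio 0.552, interval 0.271 to 1.05). The bound set beforehand, which read any interval reaching 1 as evidence against copies, was wrong because this interval also holds large differences. Attraction of the assay to strongly transcribed genes of any kind cannot be told apart from binding for the same reason: ribosomal protein and histone genes had a peak in 3 of 128 cases against 0.749% of other protein-coding genes (odds ratio 3.18, interval 0.639 to 9.69). Taken apart, ribosomal protein genes had 3 of 78 (odds ratio 5.31, interval 1.06 to 16.4, exact p = 0.0216) and histone genes 0 of 50.

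For the excess on chromosome X, extra copies of the odd-2 region are argued against, since the odds ratio without regions within 50 kb of odd-2 was 1.69 (interval 1.24 to 2.28). A coverage difference of the whole chromosome stays open: other candidate regions per Mb on X were 0.993 times those on autosomes, within the range of single autosomes (0.891 to 1.13), and their number without such a difference is not known. The test set beforehand, their median signal on X over autosomes, gave 1.00186 (0.996 in replicate 1, 1.00402 in replicate 2); it shows no shift but decides little, because the candidate sets end at a lower signal limit that holds this median in place. The uneven spread of short RNA genes met the bound set for it, with an odds ratio of 0.937 (interval 0.549 to 1.53) away from those genes. That bound counted any interval reaching 1 as a pass. This wide interval also leaves room for an excess, so the spread stays a candidate explanation only. The spread alone would not give 1 further value: tRNA genes on X also had a peak more often than those on autosomes (51 of 276, 18.5%, against 34 of 336, 10.1%, odds ratio 2.01, interval 1.23 to 3.32). A coverage difference of the whole chromosome could give this value. It would also raise X peaks away from short RNA genes, where no rise was seen (odds ratio 0.937), though that interval reaches 1.53 and leaves room for one.

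For the peaks around odd-2, extra copies of the region carried by the transgene are a candidate explanation that passed its test: the summed signal within 20 kb was above at least 99.96% of windows in both replicates, spread over 31 regions in replicate 1 and 36 in replicate 2. The signals were computed against a control. If that control carried the same copies, they would raise it too, so a high sum does not single out copies. Binding of the protein near its own gene stays open and was not tested, since copies would raise such a peak too.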
